A study of Homo sapiens with 6 samples.

How the data were processed

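RNA from 6 cultures of U937, a human myelomonocytic line that the labels list as lymphoma, was measured by sequencing of polyadenylated RNA. The groups were 2 clones that carried a control guide with no target (sgCtrl) and 4 AMBRA1 knockout clones, 2 for each of 2 guides (sgAMBRA1#1 and sgAMBRA1#2), all taken after 48 h of culture. The deposited files hold 1 library each and list 187626 transcripts with an estimated read count, a TPM value (reads per effective length, scaled to a fixed total) and an effective length in bases per transcript. Per the file headers these are salmon's estimated counts, TPM values and effective lengths, and the counts are not scaled to depth. The submitters' processing notes name Salmon 0.8.2, DESeq2 1.22.2 and GRCh38. The release of the transcript set and the strand setting are not given in the sources used here.

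Estimated counts were summed per gene with the GENCODE 29 annotation and current gene symbols. Transcripts of alternate haplotypes (15329 transcripts, 3.01% to 3.13% of the reads of a library) were added to the gene of the same symbol. A further 2354 transcripts matched no gene and were left out (0.272% to 0.336% of reads). This gave 35584 genes. The sums were rounded to whole numbers. The libraries held 18172998 to 25806250 assigned reads. A count of 0 allows up to 3 reads in a library, and this floor was used for folds against a group at 0. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

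Genes with too few reads were removed with filterByExpr (minimum count 10, 3 guide groups), which left 13025 genes. CPM values (normalised read counts scaled to a fixed library total) used TMM factors. Tests were two-sided quasi-likelihood tests of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a call at an adjusted p under 0.05. Knockout against control used genotype as the only term, so that the difference between the guides stays in the replicate spread. Each guide against control, and guide against guide, used a fit of the 3 guide groups to all 6 libraries. The common biological coefficient of variation was 30.7% in the first fit and 24.7% in the second. The labels give no batch or date.

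Before the data were examined, 27 gene lists with 843 entries were fixed from textbook knowledge of cyclin D control, autophagy, growth, stress, myeloid cells and other cell types. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry. Camera compares a list with all other genes, while fry tests whether the genes of a list move, in one direction or (mixed) in either. Members were also tested after an adjustment over the list alone.

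The rule for the named genes was fixed at the same time. It takes AMBRA1 and the D-type cyclins. For each comparison it takes the called genes with a mean of at least 1 CPM whose clones lie on the same side of both clones of the other group (up to 10 a side for the knockout and 5 a side for the guides). Where none is called, it takes the 5 with the smallest p on each side under the same conditions on CPM and clones. From each list it takes up to 4 members with the smallest p for knockout against control. Genes named outside this rule are said to be so.

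On simulated data of 13025 genes with 200 changed, 5 simulations a comparison, the knockout test recovered 65.2% of 4-fold and 8% of 2-fold changes. The guide tests recovered 68.4% to 72% of 4-fold and 16.8% to 22.6% of 2-fold changes. False calls made up 6.15% to 8.77% of all calls. A list of 40 genes shifted by 0.50 (log2) had an unadjusted camera p under 0.05 in 5 of 5 simulations with either correlation, and an unchanged list in 0 of 5. Genes were drawn independently of each other there. These simulations therefore cannot show how often either setting calls or misses a list whose genes are correlated.

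The alternatives were DESeq2 1.42.0 (default filtering, genes with at least 1 read), its size factors in edgeR, no filter, a mean of at least 1 CPM, an offset for effective length, log2(TPM + 1) with limma, a replicate block, leaving out each clone, and the mean of the guides in the fit of 3 groups. An offset for transcript GC content and length and a threshold of 0.10 were chosen after seeing the data. The correlation between the guides' effects was set beside 20 simulations without any effect that share the same controls. XIST and genes of the Y chromosome were not reported.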

Results

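The transcriptomes of 6 U937 clones were compared to ask whether loss of AMBRA1, the substrate receptor of a CRL4 ubiquitin ligase for D-type cyclins and a regulator of autophagy, alters transcription. The control clones held 24616886 and 25322346 assigned reads, the sgAMBRA1#1 clones 18172998 and 19451821, and the sgAMBRA1#2 clones 21982211 and 25806250. Between 12081 and 12736 genes had at least 10 reads per library. The first principal component held 45.1% of the variance and set the sgAMBRA1#1 clones (78.5 and 20.8) apart from the other 4 (-29.6 to -19.9). The second held 24% and was lowest in sgAMBRA1#2 clone 1 (-54.7). The correlation across genes of log2 CPM was 0.981 between the control clones and 0.964 between the clones of either AMBRA1 guide. Between clones of different groups it ranged from 0.935 (clone 1 of either guide) to 0.979 (sgCtrl clone 2 with sgAMBRA1#2 clone 2). Clones of one guide were thus not always more alike than clones of different groups.

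The transcript of the targeted gene was below both controls in all 4 knockout clones. AMBRA1 (ENSG00000110497, GRCh38 chromosome 11, 46396414 to 46594125, minus strand) stood at 31.3 ± 0.198 CPM in the controls (SD, n = 2) and 16.9 ± 8.45 CPM in the knockout clones (SD, n = 4). The sgAMBRA1#1 clones held 10.3 CPM each, 3.04-fold below the controls. The sgAMBRA1#2 clones held 19.2 and 27.9 CPM, 1.33-fold below the controls. None of these differences passed edgeR's test: the log2 fold change was -0.88 (SE 0.41, adjusted p = 0.994) for all knockout clones, -1.60 (SE 0.22, adjusted p = 0.118) for sgAMBRA1#1 and -0.41 (SE 0.21, adjusted p = 1.0) for sgAMBRA1#2. DESeq2 called AMBRA1 lower with sgAMBRA1#1 (-1.61, adjusted p = 1.38e-06), as did edgeR without the filter (-1.64, adjusted p = 0.0125), while the adjusted p was 0.0663 to 0.576 in the other 12 alternatives. The positions the guides target were not used here, and a frameshift need not lower a transcript.

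The D-type cyclins, the cell cycle regulators whose protein the ligase degrades, showed no transcript difference past the test. CCND3 (ENSG00000112576) was the most abundant, at 337 ± 139 CPM in the controls (SD, n = 2) and 368 ± 103 CPM in the knockout clones (SD, n = 4), a log2 fold change of 0.13 (SE 0.33). CCND2 (ENSG00000118971) stood at 42.0 ± 6.27 and 45.6 ± 16.9 CPM, a log2 fold change of 0.12 (SE 0.36). CCND1 (ENSG00000110092) was scarce, at 1.33 ± 0.474 and 1.18 ± 0.243 CPM, a log2 fold change of -0.18 (SE 0.40). All 3 had an adjusted p of 0.994. The sign of CCND1 turned with the effective length offset (0.46) and with TPM (0.15), and that of CCND2 with TPM (-0.03). Leaving out 1 clone turned each as well: CCND1 without sgCtrl clone 2 (0.24), CCND2 without sgCtrl clone 1 (-0.03) or sgAMBRA1#2 clone 1 (-0.07), and CCND3 without sgCtrl clone 1 (-0.24) or sgAMBRA1#1 clone 2 (-0.04). CDK6, the kinase partner of these cyclins, stood at 110 and 87.3 CPM in the controls, 33.8 and 34.0 CPM with sgAMBRA1#1, and 66.8 and 81.5 CPM with sgAMBRA1#2, and was called in no comparison by edgeR (adjusted p = 0.994 for the knockout). The list of D-type cyclins, CDK4/6, RB family and CDK inhibitors had a median log2 fold change of -0.03 over 15 genes (camera adjusted p = 0.391), and RBL2 (-0.51), CDKN2B (-0.45) and CDKN2A (0.24) did not pass.

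**Figure D1:**
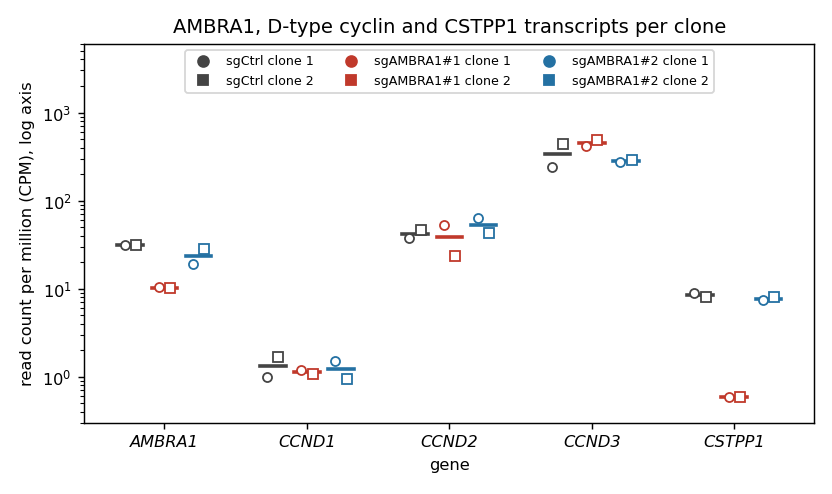
Normalised read counts (CPM, log axis) of AMBRA1, the D-type cyclins and CSTPP1 in each of the 6 clones, with bars at the group means. AMBRA1 lies at 31.1 and 31.4 CPM in the controls, 10.3 CPM in both sgAMBRA1#1 clones, and 19.2 and 27.9 CPM in the sgAMBRA1#2 clones, while CSTPP1 is below 1 CPM in the sgAMBRA1#1 clones only.

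Knockout against control tests the difference between the 4 knockout clones and the 2 controls, so a call need not hold with both guides. Genes were ranked by p among those with a mean of at least 1 CPM whose 4 knockout clones all lay above both controls. The 5 with the smallest p on this higher side were GAPT, LSP1, SERPINB2, SYTL3 and USP44, none of them called by edgeR (adjusted p = 0.994 for each). GAPT, a membrane adaptor of leukocytes, stood at 0.935 ± 0.644 CPM in the controls (SD, n = 2) and 10.3 ± 3.25 CPM in the knockout clones (SD, n = 4), a log2 fold change of 3.46 (SE 0.57). The actin-binding protein gene LSP1 stood at 30.4 ± 0.221 and 98.7 ± 29.7 CPM (1.70, SE 0.30), and SERPINB2, plasminogen activator inhibitor 2, at 41.6 ± 7.65 and 151 ± 53.1 CPM (1.86, SE 0.35). The vesicle transport gene SYTL3 (1.40, SE 0.24) and the deubiquitinase gene USP44 (2.64, SE 0.55) were the others. The 5 on the lower side, among genes with a mean of at least 1 CPM whose 4 knockout clones all lay below both controls, were PRXL2A (-2.48), TNFRSF19 (-2.17), the platelet glycoprotein gene GP1BB (-2.61), the NEDD4-ligase adaptor gene NDFIP2 (-3.13) and the lipase gene ABHD4 (-1.20). SERPINB2 lies on chromosome 18, as do NDUFV2, NDC80 and PMAIP1 of the gene lists, and the genes of this chromosome had a median 0.54 (log2) above the other libraries in sgAMBRA1#2 clone 1.

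By edgeR, 0 of 13025 genes were called for knockout against control, and 380 had an unadjusted p under 0.05 (159 higher, 221 lower), against 651 expected by chance. In 1457 genes (11.2%) the 4 knockout clones lay on the same side of both controls, where chance gives 13.3%. DESeq2 called 17 genes (9 higher, 8 lower), among them the 10 named above, and 16 of the 17 had an unadjusted p under 0.05 in edgeR. The pseudogene H3P6 was the 1 gene called with the mean of the guides in the fit of 3 groups (adjusted p = 0.0043), named after its values were seen. That call rests on 1 guide: H3P6 was listed at 0 in both sgAMBRA1#1 clones but stood at 56.5 and 61.2 CPM with sgAMBRA1#2, above both controls (48.8 and 45.7 CPM), and had an adjusted p of 0.994 in the fit of genotype. In that fit 1 gene was called without sgAMBRA1#2 clone 2.

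Among the gene lists, the transcripts encoded by mitochondrial DNA ranked lower in the knockout clones, and nuclear oxidative phosphorylation and ribosomal protein genes higher, by camera with the preset correlation. The mitochondrially encoded genes had a median log2 fold change of -0.43, with 12 of 13 members lower (adjusted p = 5.85e-06; adjusted p = 0.50 with an estimated correlation). MT-CO1 was at -0.52, MT-CO3 at -0.49, and MT-ND2 and MT-ATP6 at -0.43, each below both controls in 4 of 4 clones. Mitochondrial reads made up 2.64% and 2.20% of the control libraries, 1.61% and 1.48% of the sgAMBRA1#1 libraries and 1.91% and 1.90% of the sgAMBRA1#2 libraries. Nuclear oxidative phosphorylation genes went the other way, with a median of 0.34 and 35 of 40 higher (adjusted p = 0.00179; adjusted p = 0.673 with an estimated correlation), among them COX7A2 (0.70), NDUFV2 (0.53), NDUFA9 (0.42) and SDHB (0.41). Ribosomal protein genes had a median of 0.20 with 35 of 38 higher (adjusted p = 0.0208; adjusted p = 0.735 with an estimated correlation), with RPS14 at 0.35, RPSA at 0.31 and RPS9 at 0.27. Neither held in both guides: the per-clone medians were 0.86 and 0.44 with sgAMBRA1#1 and -0.18 and -0.02 with sgAMBRA1#2 for oxidative phosphorylation, and 0.63 and 0.38 against -0.37 and 0.02 for ribosomal proteins. The mitochondrial call held in 15 of 15 alternatives that kept the preset correlation. The oxidative phosphorylation call was lost without sgAMBRA1#1 clone 1 (adjusted p = 0.148), and the ribosomal protein call with the offset for GC content and length (0.175) and without sgAMBRA1#1 clone 1 (0.805), its clone 2 (0.28), sgCtrl clone 1 (0.136) or sgCtrl clone 2 (0.0615).

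**Figure D2:**
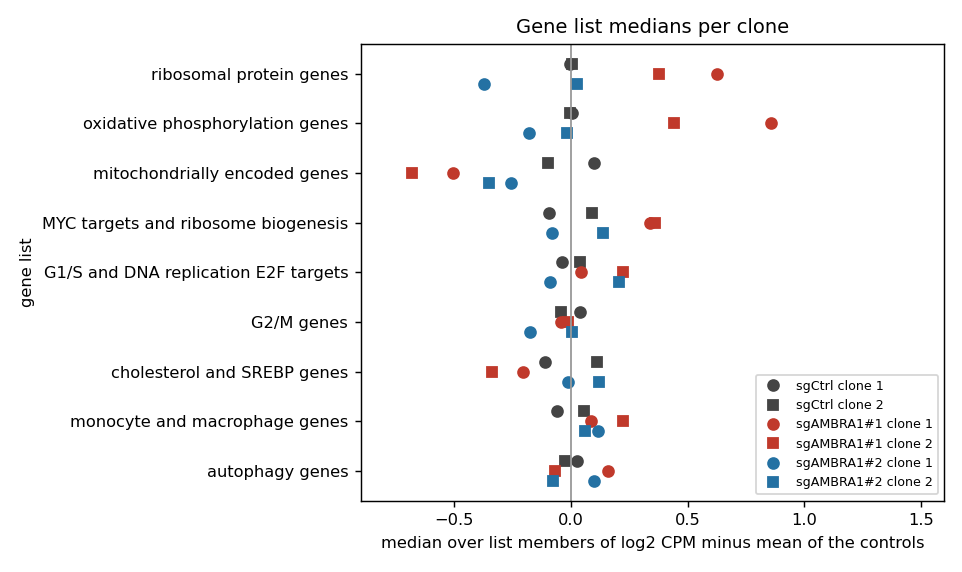
Median over the members of 9 gene lists of log2 CPM minus the mean of the controls, for each of the 6 clones, with clone 1 as circles and clone 2 as squares. The sgAMBRA1#1 clones lie above the controls for ribosomal protein (0.63 and 0.38) and oxidative phosphorylation genes (0.86 and 0.44), and all 4 knockout clones lie below them for mitochondrially encoded genes (-0.68 to -0.26).

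E2F targets, MYC targets and histone genes ranked higher in camera, and G2/M genes were not called. For the histone genes, how completely the selection of polyadenylated RNA captured their transcripts was not tested. E2F targets of G1/S and DNA replication had a median log2 fold change of 0.13 with 49 of 65 higher (adjusted p = 0.00655; adjusted p = 0.673 with an estimated correlation), including CLSPN (0.64), POLE2 (0.47), GINS2 (0.46) and E2F2 (0.40). MYC targets and ribosome biogenesis genes had a median of 0.18 with 34 of 40 higher (adjusted p = 0.00655; adjusted p = 0.673 with an estimated correlation), including MRTO4 (0.51), RRP9 (0.47), BOP1 (0.42) and PES1 (0.28). The replication-dependent histone genes had a median of 0.32 with 14 of 18 higher (adjusted p = 0.038; adjusted p = 0.599 with an estimated correlation), with H2BC17 at 1.33, H4C5 at 1.71, H2AC20 at 0.82 and H1-4 at 0.70, at 3.74 CPM or less in a clone. G2/M genes had a median of -0.06 with 33 of 50 lower (adjusted p = 0.299), with ESPL1 at -0.42, BUB1 at -0.31, DLGAP5 at -0.28 and NDC80 at 0.37. The E2F and MYC calls were lost without sgCtrl clone 1 (adjusted p = 0.386 and 0.47), sgAMBRA1#1 clone 2 (0.102 for both) or sgAMBRA1#2 clone 2 (0.219 and 0.0556), and the camera direction of the G2/M genes turned without sgAMBRA1#2 clone 1 (0.883). The histone call was lost with DESeq2's values (0.0854), a mean of at least 1 CPM (0.416) and the offset for GC content and length (0.181), and without sgCtrl clone 1 (0.47) or sgAMBRA1#1 clone 2 (0.102), and the histone median of sgAMBRA1#2 clone 1 was -0.22. That clone was also below both controls for E2F targets (-0.09) and between them for MYC targets (-0.08), and neither list was called for sgAMBRA1#2 alone (adjusted p = 0.0814 and 0.32).

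Myeloid and stress lists were mixed. Monocyte and macrophage genes had a median log2 fold change of 0.26 with 25 of 35 higher (camera adjusted p = 0.0282; adjusted p = 0.599 with an estimated correlation). In this list S100A9 (2.12), CCR2 (1.63) and the NADPH oxidase subunit gene NCF1 (1.17) were above, and the aminopeptidase gene ANPEP (-0.81) below, both controls in 4 of 4 clones. Granulocyte and progenitor genes had a median of -0.10 with 12 of 19 lower (adjusted p = 0.0466; adjusted p = 0.599 with an estimated correlation), including MYB at -0.41, which stood at 490 and 464 CPM in the controls and 319 to 432 CPM in the knockout clones. FLT3 (1.56 and 1.79 CPM in the controls, 0 to 0.757 CPM in the knockout clones) and BPI (0.679 and 1.03 CPM, then 0.0378 to 0.356 CPM) were near the detection limit, and RUNX1 was at 0.64. ANPEP lies on chromosome 15 (median -0.61 in sgAMBRA1#1 clone 1) and BPI on chromosome 20 (-0.46 in sgAMBRA1#2 clone 1). Among p53 targets the median was 0.17 with 19 of 24 higher (adjusted p = 0.0123; adjusted p = 0.50 with an estimated correlation), with TIGAR (1.52) and PLK3 (0.46) above both controls in 4 of 4 clones, and GDF15 (1.86) and FDXR (0.49) in 3. ATF4 and unfolded protein response genes had a median of 0.21 with 23 of 30 higher (adjusted p = 0.00655; adjusted p = 0.599 with an estimated correlation), including STC2 (1.30), SESN3 (0.85), DDIT3 (0.72) and SLC3A2 (0.40). Immediate early and stress genes had a median of 0.16 with 17 of 28 higher (adjusted p = 0.038; adjusted p = 0.673 with an estimated correlation), with HMOX1 at 1.10, HSPA1A at 0.61, DUSP6 at 0.46 and JUN at -0.60. The erythroid and megakaryocyte list held 5 tested genes, with a median of 0.14 and 4 higher (adjusted p = 0.0393; adjusted p = 0.599 with an estimated correlation): SLC4A1 was at 1.37, KLF1 at 0.59, NFE2 at 0.05 and EPOR at -0.08. The sign of NFE2 turned with TPM (-0.03), without sgCtrl clone 1 (-0.09) and without sgAMBRA1#1 clone 2 (-0.00), and that of EPOR without sgCtrl clone 1 (0.27), sgAMBRA1#1 clone 2 (0.04) or sgAMBRA1#2 clone 2 (0.02).

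Several of these calls did not hold under other settings. The granulocyte call held in 5 of 15 alternatives with the preset correlation. It was lost with no filter (adjusted p = 0.24), a mean of at least 1 CPM (0.446), the effective length offset (0.059), the replicate block (0.0526) and the mean of the guides (0.0897), and without either sgCtrl clone (0.428 and 0.192), sgAMBRA1#1 clone 2 (0.28) or either sgAMBRA1#2 clone (0.0878 and 0.536). The erythroid call held in 6 of 15. It was lost with DESeq2's values (0.113), no filter (0.236), a mean of at least 1 CPM (0.302), the effective length offset (0.0568) and TPM (0.0894), and without sgCtrl clone 1 (0.386), either sgAMBRA1#1 clone (0.0681 and 0.102) or sgAMBRA1#2 clone 1 (0.09). The immediate early call held in 9 of 15. Its direction turned to lower without sgCtrl clone 1 (0.47), and it was lost with no filter (0.0986) and the effective length offset (0.0573), and without sgAMBRA1#1 clone 2 (0.28) or either sgAMBRA1#2 clone (0.0842 and 0.0748). The monocyte call was lost without sgCtrl clone 1 (0.286), sgAMBRA1#1 clone 2 (0.102) or sgAMBRA1#2 clone 1 (0.09), the p53 call with no filter (0.0563) and without sgCtrl clone 1 (0.21), and the ATF4 call without sgCtrl clone 1 (0.575).

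The clones did not all agree either. For granulocyte genes sgAMBRA1#1 clone 1 had a median of 0.24, above both controls, against -0.55 to -0.14 in the other 3 knockout clones, and the list was called for sgAMBRA1#2 (adjusted p = 0.0308) but not for sgAMBRA1#1 (0.538). Both sgAMBRA1#2 clones (0.04 and 0.18) lay between the controls (-0.19 and 0.19) for immediate early genes, as did sgAMBRA1#1 clone 2 (0.13) and sgAMBRA1#2 clone 1 (-0.07) between theirs (-0.15 and 0.15) for ATF4 genes, and clone 2 of either guide (0.08 and 0.06) between -0.08 and 0.08 for p53 targets. For sgAMBRA1#1 and sgAMBRA1#2 alone the adjusted p was 0.156 and 0.124 for immediate early, 0.0642 and 0.0971 for ATF4, 0.0764 and 0.0814 for p53, 0.0764 and 0.16 for erythroid and 0.0488 and 0.168 for monocyte genes.

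The lists closest to AMBRA1's own functions were not called by camera on edgeR's log2 CPM over all 6 libraries. The CRL4 ligase and AMBRA1 partners had a median log2 fold change of 0.01 (adjusted p = 0.926), with DET1 at -0.82, CRBN at 0.31, PPP2CB at 0.29 and CUL4B at -0.27. Autophagy genes had a median of 0.01 (adjusted p = 0.968), with ULK1 at -0.42, ATG5 at 0.41, ATG4B at 0.33 and BNIP3 at 0.28. Lysosome genes had a median of -0.09 (adjusted p = 0.0614), and GAA (-0.91), GALNS (-0.44), LIPA (-0.31) and GUSB (-0.29) were each below both controls in 4 of 4 clones. Lysosome genes were called lower with DESeq2's values (adjusted p = 0.0339) and without sgAMBRA1#1 clone 1 (0.0105) or sgAMBRA1#2 clone 1 (0.0216). The direction of the autophagy list turned to lower in 6 of 15 alternatives and that of the ligase list in 2, none of them called. DET1 lies on chromosome 15.

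Other lists of signalling, death and metabolism were not called on the same values. HLA class II and antigen presentation genes had a median log2 fold change of 0.02 with a camera direction of lower (adjusted p = 0.31): CD74 stood at 62.0 and 46.1 CPM in the controls and 0 to 16.8 CPM in the knockout clones, HLA-DRA at 2.96 and 0.755 CPM against 0 to 0.266 CPM, CIITA was at -0.94 and PSMB9 at 0.68. Adjusted over the list alone, 1 gene of this list passed, HLA-DRA, and 0 in each of the other 26 lists. With the mean of the guides in the fit of 3 groups, 10 mitochondrially encoded and 2 monocyte genes passed in this way. So did 1 gene each of the D-type cyclin, HLA class II and epithelial lists. NF-kB and inflammatory genes had a median of 0.25 (adjusted p = 0.0844), with CCL2 at 2.03, IL1RN at 1.65, IER3 at 1.5 and CXCL8 at 1.07. The apoptosis and BCL2 family had a median of 0.16 (adjusted p = 0.0603), with PMAIP1 at 0.65, CASP8 at 0.46, BID at 0.39 and BCL2L2 at 0.32. Type I interferon response genes had a median of -0.01 with a camera direction of higher (adjusted p = 0.987), with XAF1 at 1.51, TRIM22 at 1.26, MX1 at -0.73 and STAT2 at -0.56. Cholesterol and SREBP genes had a median of -0.06 (adjusted p = 0.288), with FASN at -0.80, FADS1 at -0.45, HMGCS1 at 0.35 and MVD at 0.31. Glycolysis and hypoxia genes had a median of -0.06 (adjusted p = 0.364), with ALDOC at -1.86, PFKP at -0.42, SLC2A3 at 0.26 and MXI1 at -0.24. Cell adhesion and integrin genes had a median of -0.05 (adjusted p = 0.968), with CD81 at 1.45, ITGAL at 1.28, CD9 at -0.76 and ZYX at 0.25. Some passed under other settings: NF-kB genes ranked higher with the effective length offset (adjusted p = 0.0272), TPM (0.0167) and without sgCtrl clone 2 (0.023) or sgAMBRA1#1 clone 1 (0.0462), and apoptosis genes with the mean of the guides (0.0394) and the offset for GC content and length (0.025). Cholesterol genes ranked lower without sgCtrl clone 1 (0.0343) or sgAMBRA1#2 clone 2 (0.0362) and turned without sgCtrl clone 2 (0.836), while HLA class II genes ranked lower without sgCtrl clone 2 (0.0363) and turned without sgCtrl clone 1 (0.833). The direction of the interferon and adhesion lists turned in 7 of 15 alternatives each, none of them called.

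Marker lists of other cell types held few tested genes. T and NK cell genes had a median log2 fold change of 0.43 over 6 genes (camera adjusted p = 0.437), with NCAM1 at 1.74, KLRB1 at 1.62, LAT at -1.55 and NKG7 at 0.28. B cell genes had a median of -0.44 over 7 genes (adjusted p = 0.189), with PAX5 at -0.64 and CD22 and POU2AF1 at -0.49. Epithelial and fibroblast genes had a median of -0.09 over 7 genes (adjusted p = 0.276), with FBN1, on chromosome 15, at -1.47, MUC1 at -0.86, PDGFRB at -0.63 and LAMB3 at 0.60. The sign turned for CD22 (0.01) and PDGFRB (0.27) with the effective length offset, for PDGFRB with TPM (0.06), and for POU2AF1 without sgCtrl clone 2 (0.09). B cell genes were called lower without sgCtrl clone 2 (adjusted p = 0.0398) or sgAMBRA1#1 clone 1 (0.0462), epithelial and fibroblast genes lower without sgAMBRA1#2 clone 1 (0.0326), and the direction of the T and NK cell list turned without sgCtrl clone 1 (0.606).

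In all, camera called 12 of the 27 lists for knockout against control with the preset correlation (10 higher, 2 lower). With an estimated correlation it called 0, and the lowest adjusted p was 0.50. Among the 12, the estimate lay above the preset 0.01 except for p53 targets (-0.0092). It was 0.85 for ribosomal protein, 0.64 for oxidative phosphorylation, 0.31 for MYC, 0.25 for E2F and 0.18 for mitochondrially encoded genes. A preset below the true correlation makes p too small for such lists. By fry 0 were called in one direction (lowest adjusted p = 0.202) and 0 in its mixed test, which counts members moving either way (lowest adjusted p = 0.749). The count was 3 without sgCtrl clone 1 and 4 without sgAMBRA1#1 clone 2.

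The first guide alone against control asks what its clones share. Transcripts of CSTPP1, which encodes a regulator of tubulin polyglutamylation at centriolar satellites, and of the pseudogene H3P6 were estimated lower in both sgAMBRA1#1 clones. CSTPP1 (ENSG00000149179, chromosome 11, 46936689 to 47164385, plus strand), 343 kb from AMBRA1, stood at 8.47 ± 0.734 CPM in the controls and 0.589 ± 0.00697 CPM in the sgAMBRA1#1 clones (SD, n = 2 each), 14.2-fold lower (log2 -3.83, SE 0.32, adjusted p = 0.0436). The fitted difference was smaller and not called with the effective length offset (log2 -2.62, adjusted p = 0.10) and with limma on log2(TPM + 1) (-2.16, adjusted p = 0.0522). The added 1 shrinks the difference of a gene this scarce, so the last value does not measure a smaller loss. H3P6 (ENSG00000235655, chromosome 2, 174719908 to 174720318), a processed pseudogene of a histone H3 gene, was at 47.2 ± 2.14 CPM in the controls and listed at 0 in both sgAMBRA1#1 clones. With a floor of 3 counts per library it was at least 280-fold lower (adjusted p = 0.000885), a bound that covers counting error only. Whether its reads were assigned to a similar histone H3 gene was not tested. Genes between AMBRA1 and CSTPP1 varied: ATG13 was at -0.15, ARHGAP1 at -0.995 and CKAP5 at -0.75. LRP4, also between them, was at 3.37 (SE 2.14), with 2.14 CPM in sgAMBRA1#1 clone 1 and 0.0531 CPM in its clone 2. ARFGAP2, just beyond CSTPP1, was at -0.03. All of these were named after their values were seen.

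**Figure D3:**
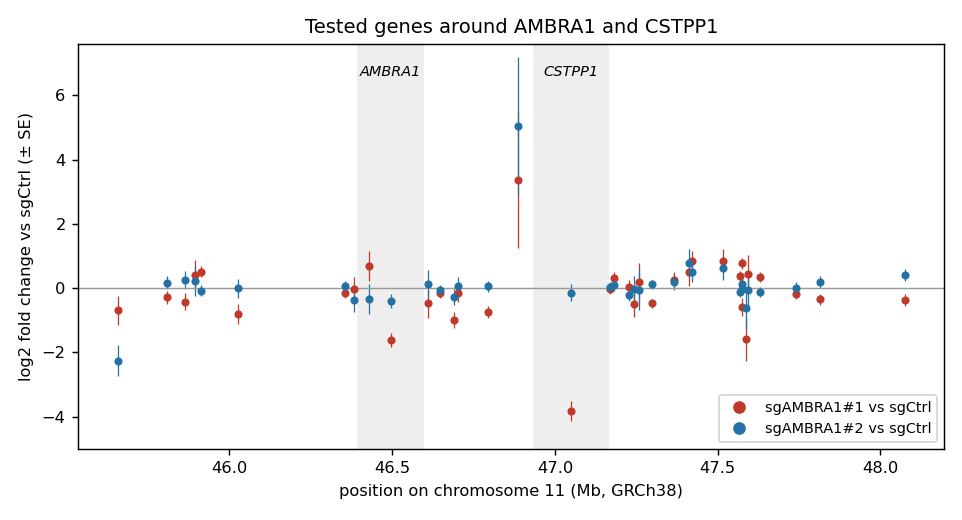
Log2 fold change against the controls, with its SE, of each tested gene within 1 Mb of AMBRA1 or CSTPP1 on chromosome 11 (GRCh38), for sgAMBRA1#1 and sgAMBRA1#2. With sgAMBRA1#1, CSTPP1 lies at -3.83 and AMBRA1 at -1.60, and the 34 other genes have a median of -0.09.

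Of the gene lists, 8 were called by camera for sgAMBRA1#1 with the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.802). By fry 0 were called in one direction (lowest adjusted p = 0.163) and 15 in its mixed test (lowest adjusted p = 0.0068). That lowest value was shared by the D-type cyclin, monocyte and erythroid lists. The mixed test also called the CRL4 ligase and AMBRA1 partners (0.0286), autophagy genes (0.0379) and lysosome genes (0.0286). This test does not compare a list with other genes. In edgeR 5 of 21, 8 of 41 and 6 of 33 members had an unadjusted p under 0.05, against 22.6% of all genes. Camera, which makes that comparison, called none of them (adjusted p = 0.729, 0.897 and 0.473). The mixed calls therefore do not set these lists apart from other genes. Oxidative phosphorylation genes (median log2 0.66, 38 of 40 higher, adjusted p = 5.95e-10; adjusted p = 0.802 with an estimated correlation) and ribosomal protein genes (0.50, 37 of 38 higher, adjusted p = 6.63e-09; adjusted p = 0.83 with an estimated correlation) ranked highest. Adjusted over the list alone, 28 of the former and 14 of the latter passed. The estimated correlation was 0.52 among the former and 0.74 among the latter, far above the preset 0.01, so their preset p is too small. MYC targets (0.36, adjusted p = 0.00476), histone genes (0.49, adjusted p = 0.0306), E2F targets (0.15, adjusted p = 0.0347) and monocyte genes (0.23, adjusted p = 0.0488) also ranked higher, with adjusted p = 0.802 for histone and monocyte genes and 0.83 for MYC and E2F targets with an estimated correlation. Mitochondrially encoded genes (-0.54, adjusted p = 0.000299; adjusted p = 0.802 with an estimated correlation) and cholesterol genes (-0.21, adjusted p = 0.0182; adjusted p = 0.83 with an estimated correlation) ranked lower, and 11 cholesterol genes passed over the list alone. GC content and length explained 13% and 8.37% of the variance of the sgAMBRA1#1 libraries across genes, 8.42% and 4.19% of that of the sgAMBRA1#2 libraries, and 4.27% and 2.77% of that of the controls.

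By edgeR, 2 of 13025 genes were called for sgAMBRA1#1, both lower, while 2941 had an unadjusted p under 0.05 (1474 higher, 1467 lower; 651 expected by chance). In 60.7% of genes both clones lay on the same side of both controls, where chance gives 33.3%. DESeq2, with 21990 genes in place of 13025, called 1458 genes (701 higher, 757 lower), and edgeR without the filter, on the same 21990, called 162 (48 higher, 114 lower). The edgeR count was 90 without sgAMBRA1#1 clone 2 and 1 without sgAMBRA1#1 clone 1, sgCtrl clone 1 or sgCtrl clone 2, and CSTPP1 was not called in 9 alternatives (adjusted p = 0.05 to 0.399), with adjusted p = 0.399 without sgCtrl clone 1, 0.298 without sgCtrl clone 2, 0.245 without sgAMBRA1#1 clone 1, 0.071 without sgAMBRA1#2 clone 1 and 0.0618 without sgAMBRA1#2 clone 2.

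The second guide alone against control asks the same of the sgAMBRA1#2 clones. PSTPIP2, a membrane-bending adaptor of myeloid cells, stood at 10.8 ± 2.49 CPM in the controls and 0.105 ± 0.0952 CPM in the sgAMBRA1#2 clones (SD, n = 2 each), with 541 against 5 reads, a ratio of 107 (95% counting interval 45.5 to 331), and was not called (log2 -6.65, SE 0.57, adjusted p = 0.114). The platelet-activating factor receptor gene PTAFR (-1.07, SE 0.14), the granule ribonuclease gene RNASE3 (-1.18, SE 0.16), the pseudogene SIGLEC17P (-1.82, SE 0.27) and ZACN were the others with the smallest p on the lower side, among genes with a mean of at least 1 CPM and both clones below both controls. ZACN, a ligand-gated channel gene that overlaps SRP68 and EXOC7, had 85 reads in the controls and 3 with sgAMBRA1#2, a ratio of 28 (95% counting interval 9.26 to 138); whether these are reads of the overlapping genes was not tested. On the higher side, among genes with both clones above both controls, were GAPT (3.63, SE 0.60), the integrin gene ITGAL (1.85, SE 0.34), SERPINB2 (1.49, SE 0.27), LSP1 (1.40, SE 0.23) and TAGAP (1.16, SE 0.22). Camera called 3 lists, all lower: mitochondrially encoded genes (-0.34, 13 of 13, adjusted p = 0.000171), ribosomal protein genes (-0.15, 38 of 38, adjusted p = 0.00187) and granulocyte genes (-0.22, 15 of 19, adjusted p = 0.0308), each with adjusted p = 0.894 with an estimated correlation. The ribosomal protein median was -0.37 in clone 1 but 0.024 in clone 2, above both controls (-0.003 and 0.003). By fry 0 lists were called in one direction or mixed (lowest adjusted p = 0.598 and 0.452). PSTPIP2 and SERPINB2 lie on chromosome 18, whose median was 0.54 higher in sgAMBRA1#2 clone 1.

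By edgeR, 0 genes were called for sgAMBRA1#2 (lowest adjusted p = 0.114), and 483 had an unadjusted p under 0.05 (220 higher, 263 lower; 651 expected by chance). Both clones lay on the same side of both controls in 33.5% of genes, where chance gives 33.3%. DESeq2 called 42 genes (17 higher, 25 lower) and edgeR without the filter 2. Leaving out sgAMBRA1#2 clone 1 gave 6 and leaving out clone 2 gave 5.

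The guides were compared directly to test whether their effects differ. H3P6, CSTPP1 and ZACN differed. H3P6 stood at 58.8 ± 3.38 CPM with sgAMBRA1#2 (SD, n = 2) and was listed at 0 with sgAMBRA1#1, at least 349-fold lower (adjusted p = 0.000726). The assignment of its reads stays open as above. CSTPP1 was 12.9-fold higher with sgAMBRA1#2, at 7.66 ± 0.404 against 0.589 ± 0.00697 CPM (SD, n = 2 each; log2 3.69, SE 0.31, adjusted p = 0.0366). ZACN stood at 21.3 and 13.2 CPM with sgAMBRA1#1 and 0.0431 and 0.0757 CPM with sgAMBRA1#2 (adjusted p = 0.0072), 607 against 3 reads, a ratio of 282 (95% counting interval 95.9 to 1370), with the origin of the reads open as above. AMBRA1 itself was 2.29-fold higher with sgAMBRA1#2 (log2 1.20, SE 0.22, adjusted p = 0.0678), which did not pass.

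By camera, ribosomal protein genes (median log2 -0.68, 37 of 38 lower with sgAMBRA1#2, adjusted p = 2.62e-11) and oxidative phosphorylation genes (-0.67, 38 of 40 lower, adjusted p = 9.22e-11) were lower with sgAMBRA1#2 than with sgAMBRA1#1, and cholesterol and SREBP genes higher (0.35, 23 of 29, adjusted p = 0.00629). Each had adjusted p = 0.926 with an estimated correlation. That correlation was 0.74, 0.52 and 0.27 in this order, far above the preset 0.01. By fry 0 lists were called in one direction (lowest adjusted p = 0.275) and 12 in its mixed test (lowest adjusted p = 0.0103). The mixed test called the D-type cyclin list (0.0271), the CRL4 ligase and AMBRA1 partners (0.0295) and autophagy genes (0.0295), but not lysosome genes (0.157). It does not compare a list with other genes, and 27.7% of all genes had an unadjusted edgeR p under 0.05. Camera did not call these lists (adjusted p = 0.888 for D-type cyclins, 0.817 for the ligase and 0.871 for autophagy). Adjusted over the list alone, 32 ribosomal protein, 28 oxidative phosphorylation and 13 cholesterol genes passed. In the first list RPS14 was at -0.82, in the second COX7A2 at -0.78, and in the third FASN at 0.93 and FADS1 at 0.76.

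By edgeR, 3 genes were called between the guides (2 higher, 1 lower with sgAMBRA1#2), 1778 had an adjusted p under 0.10 (851 higher, 927 lower), and 3611 an unadjusted p under 0.05. Limma on log2(TPM + 1) called 1470, of which 1317 were higher and 153 lower. Its TPM values were scaled to a fixed total without TMM or size factors, so this uneven split cannot be read as a one-sided difference. DESeq2 called 2240 (1163 higher, 1077 lower), edgeR without the filter 873 (498 higher, 375 lower) and edgeR with the effective length offset 722 (376 higher, 346 lower). The count was 826 without sgAMBRA1#1 clone 2, 1 without sgAMBRA1#1 clone 1, 13 without sgAMBRA1#2 clone 1 and 10 without sgAMBRA1#2 clone 2. The replicate block also gave 3, but 1 higher and 2 lower. CSTPP1 was not called with that block (adjusted p = 0.0679), nor without sgCtrl clone 1 (0.137), sgCtrl clone 2 (0.119), sgAMBRA1#1 clone 1 (0.216) or sgAMBRA1#2 clone 2 (0.0517), nor was ZACN without sgAMBRA1#1 clone 1 (0.0739), while H3P6 was.

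Across 13025 genes, the log2 fold changes of the guides against the shared controls correlated with a Pearson r of 0.273 and a Spearman rho of 0.104, with genes not being independent replicates. Simulated groups with no effect, which share the same controls, gave 0.497 and 0.462. These simulations gave all clones the same spread per gene. In the data 605 genes differed over 2-fold between the controls, against 1224 between the sgAMBRA1#1 and 1232 between the sgAMBRA1#2 clones. Less spread in the controls lowers the agreement expected without an effect. The simulated values here and below therefore cannot show whether the guides agree more or less than noise would. The signs matched in 50.4% of genes, against 66.6% in the simulations. At an unadjusted p under 0.05, 56 genes were higher with both guides (24.9 for independent lists, 84 in the simulations) and 87 lower with both (29.6 and 53.5). With a separate control clone for each guide, r was 0.00411 or 0.08, and over genes with a mean of at least 10 CPM it was 0.097. It was 0.164 without sgAMBRA1#2 clone 2 and 0.452 without sgCtrl clone 2.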

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

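The tests of this part were stated before their results were seen, except that the correction for GC content and length and the threshold of 0.10 were chosen after seeing the data.

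The first pattern is the lower level of CSTPP1, with AMBRA1, in both sgAMBRA1#1 clones, and CSTPP1 differed between the guides by 3.69 (log2, edgeR). Assignment of its reads to an overlapping gene was not seen, but it stays open. The overlapping genes gained 0% of the 7.88 CPM lost: ARFGAP2 changed by -2.1 CPM (SE 3.45), and ENSG00000271350 was at 0 CPM with sgAMBRA1#1 and in the controls. With the SE of ARFGAP2 added, the gain was at most 17.1% of the loss, but that margin is too narrow to exclude a larger gain. Loss of a copy of the surrounding segment stays open for AMBRA1. The 34 other genes within 1 Mb had a median log2 fold change of -0.0855 (95% bootstrap interval -0.329 to 0.314). That interval lies above the -0.50 stated for such a loss but does not meet the bound stated against it. Of these genes, 6 lay below -0.50, ARHGAP1 and CKAP5 among them. Loss of a copy with at least 1 other left lowers a transcript at most about 2-fold, if its level follows the number of copies. CSTPP1 was 14.2-fold lower (log2 -3.83, SE 0.32, and -2.16 on log2(TPM + 1), where the added 1 shrinks it). This argues against such a loss as its whole cause. A smaller rearrangement at the edited site or a difference between founder cells may also be at work, and neither was tested. An effect of AMBRA1 itself on CSTPP1 stays open too, although the sgAMBRA1#2 clones, with 19.2 and 27.9 CPM of AMBRA1, held 7.38 and 7.95 CPM of CSTPP1.

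The second pattern is the distance of the sgAMBRA1#1 clones from the sgAMBRA1#2 clones, seen in the medians of ribosomal protein (-0.68), oxidative phosphorylation (-0.67) and cholesterol genes (0.35, sgAMBRA1#2 minus sgAMBRA1#1). Lower depth was not settled. Thinning all libraries to 18111736 reads left 100% (99.5 to 101) of the median difference of the 1778 genes with an adjusted p under 0.10. At that depth 1732 genes were under 0.10 and 4 were called. Thinning keeps each gene's expected share of the reads, so the median difference was bound to stay and cannot decide the question. A bias by transcript GC content or length may account for part: 54.7% (53 to 56) of that difference (0.856 before, log2) was left after the correction, the genes under 0.10 went from 1778 to 4, and the 3 calls at 0.05 numbered 3 again. For the 78 ribosomal protein and oxidative phosphorylation genes 38.5% (30.3 to 48.2) was left, a median of -0.26 in place of -0.67 with 70 in place of 75 lower, so such a bias is a candidate explanation for most of their shift. The correction also removes any true change that follows GC content or length, and the guide is confounded with the clones, so a difference in AMBRA1 dose or in founder cells stays open and untested.

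Of the 15 splits of the 6 libraries into 4 and 2, 6 gave at least the 380 genes at an unadjusted p under 0.05 of the real split. The splits are too few for a share under 0.05. The highest other value was 4206, from the sgAMBRA1#1 clones against the other 4 libraries, which also called 1484 genes and points to a structure of the samples.

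H3P6 differed between the guides, with a fitted log2 difference of 13.38 that depends on the prior count and is no bound. By counting error alone its level was at least 349-fold lower with sgAMBRA1#1. Assignment of its reads to a similar histone H3 gene was not tested and stays open. ZACN differed by -8.03 (log2, sgAMBRA1#2 minus sgAMBRA1#1), a fitted value that rests on 3 reads in the sgAMBRA1#2 clones. Assignment of reads of SRP68 or EXOC7, which overlap ZACN, was not tested and stays open.

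Single knockout clones stood far from the other 3 for 5 of the 164 gene values and list medians tested, where chance gives about 1 in 20. HLA-DRA was at 0.266 CPM in sgAMBRA1#1 clone 2 and 0 to 0.0431 CPM in the others. MVD was at 81.6 CPM in sgAMBRA1#1 clone 1 and 59.1 to 60.4 CPM in the others. PMAIP1 was at 30.4 CPM in sgAMBRA1#1 clone 1 and 14.3 to 16.4 CPM in the others. ZYX was at 481 CPM in sgAMBRA1#2 clone 1 and 363 to 371 CPM in the others. NCAM1 was at 3.49 CPM in sgAMBRA1#2 clone 1 and 0.159 to 0.713 CPM in the others.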

How the results depend on the processing

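The offset for GC content and length and the threshold of 0.10 were chosen after seeing the data, and all other alternatives before. AMBRA1 was lower in the knockout clones under every alternative run (log2 -1.24 to -0.61) and past the threshold in none (adjusted p = 0.361 to 1.0). Over the 137 named results and 2033 alternatives, 1983 kept direction and side of the threshold, 16 passed it newly, 15 no longer passed it and 19 reversed. What caused the changes below was not tested, except where fewer or more genes or samples enter by construction. On simulated data the knockout test recovered 8% and the tests of 2 clones a group 16.8% to 22.6% of 2-fold changes, so such changes can be missed.

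DESeq2 called 17 genes for knockout against control, 1458 for sgAMBRA1#1, 42 for sgAMBRA1#2 and 2240 between the guides, against 0, 2, 0 and 3 with edgeR. Without the filter the guide counts were 162, 2 and 873. With the effective length offset they were 1 for sgAMBRA1#1 and 722 between the guides, and with limma on log2(TPM + 1) 4 and 1470. A mean of at least 1 CPM and the replicate block each gave 1 for sgAMBRA1#1, and between the guides the block gave 3 (1 higher, 2 lower) without CSTPP1 (adjusted p = 0.0679). The mean of the guides in the fit of 3 groups gave 1 gene for the knockout, and the threshold of 0.10 gave 1778 between the guides. The offset for GC content and length left each of the 4 gene counts as it was, but ended the knockout calls of ribosomal protein (adjusted p = 0.175) and histone genes (0.181) and added that of apoptosis genes (0.025). With an estimated correlation 0 lists were called in place of 12. The correlation of the guides' effects, 0.273, was 0.097 at 10 CPM or more, 0.00411 and 0.08 with separate control clones and 0.336 with the offset for GC content and length.

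Leaving out each clone in turn, where a lone clone is assumed to vary like the other groups, gave 0 to 1 genes for the knockout (1 without sgAMBRA1#2 clone 2), 1 to 90 for sgAMBRA1#1 (90 without its clone 2; 1 without its clone 1 or either control), 0 to 6 for sgAMBRA1#2 (6 without its clone 1, 5 without its clone 2) and 1 to 826 between the guides (1 without sgAMBRA1#1 clone 1, 826 without its clone 2, 13 and 10 without sgAMBRA1#2 clones 1 and 2). The D-type cyclins spanned -0.505 to 0.238 (CCND1), -0.069 to 0.34 (CCND2) and -0.243 to 0.627 (CCND3), POU2AF1 -0.901 to 0.088, NFE2 -0.092 to 0.218 and EPOR -0.365 to 0.266. Leaving out clones gave 3 to 13 lists (3 without sgCtrl clone 1, 4 without sgAMBRA1#1 clone 2) and correlations of 0.164 (without sgAMBRA1#2 clone 2) to 0.452 (without sgCtrl clone 2).

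Signs reversed, always among knockout values past no threshold, as follows. With the effective length offset CCND1 was at 0.46, CD22 at 0.007 and PDGFRB at 0.27, and with TPM CCND1 at 0.15, CCND2 at -0.026, NFE2 at -0.028 and PDGFRB at 0.061. With the mean of the guides ZACN was at -0.672. Without sgCtrl clone 1 CCND2 was at -0.028, CCND3 at -0.243, NFE2 at -0.092 and EPOR at 0.266, and without sgCtrl clone 2 CCND1 at 0.238 and POU2AF1 at 0.088. Without sgAMBRA1#1 clone 2 CCND3 was at -0.037, NFE2 at -0.003 and EPOR at 0.04. Without sgAMBRA1#2 clone 1 CCND2 was at -0.069, and without its clone 2 EPOR at 0.016.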

Other observations

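The tests of whole chromosomes 15, 18 and 20 were chosen after the medians of these chromosomes were seen, and they were split by chromosome and given a condition on the interval after the values of the bins were seen too. The share of variance by chromosome was stated as a test before.

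Beyond the genes of the fixed rule, the genes that DESeq2 called for knockout against control, chosen here after their values were seen, numbered 7. TNFSF13B, the cytokine BAFF, stood at 78.1 and 44.8 CPM in the controls and 123 to 244 CPM in the knockout clones (log2 1.54, adjusted p = 0.0493). The adhesion receptor gene CD48 stood at 0.0799 and 0.119 CPM in the controls and 0.833 to 9.45 CPM in the knockout clones (adjusted p = 0.0199), and NLRP7 at 2.83 and 3.14 against 5.74 to 8.08 CPM (adjusted p = 0.0395). GLUL, glutamine synthetase, was lower, at 873 and 717 CPM in the controls and 460 to 490 CPM in the knockout clones (log2 -0.76, adjusted p = 0.0199), as was the transcription factor gene EBF4 (-2.06, adjusted p = 0.038). MAGED1 was called lower but stood at 59.9 CPM in one control and 2.15 CPM in the other. ENSG00000267303 was called higher but was listed at 0 in both controls and both sgAMBRA1#2 clones, with 93.6 and 33.5 CPM in the sgAMBRA1#1 clones. None of these genes was called by edgeR.

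The third pattern is a shift of whole chromosomes in single clones: of 138 pairs of library and chromosome, 3 had a median beyond 0.30 (log2) from the other 5 libraries, and the next highest was 0.21. In sgAMBRA1#2 clone 1, 87.6% of 161 genes of chromosome 18 were higher (median 0.54, 0.35 in the weakest of 4 bins along the chromosome, 95% interval 0.20 to 0.56) and 81.5% of 319 genes of chromosome 20 lower (median -0.46, weakest bin -0.38, -0.45 to -0.29), which is consistent with a gain and a loss of a copy. In sgAMBRA1#1 clone 1, 77.1% of 401 genes of chromosome 15 were lower (median -0.61), but the first bin was at -0.10 (-0.32 to 0.06), which argues against a shift of the whole chromosome under the bound as first written (within 0.15 of 0), while the interval, added later, keeps it open. GC content or length is argued against as the whole cause, since 84.1%, 120% and 84.8% of the medians of chromosomes 18, 20 and 15 were left after the correction. Chromosome explained at most 3.98% of the variance across genes of any clone (highest of 100 permutations 0.428% in that clone), so such shifts do not account for most of the difference between the clones of one guide, and no DNA measurement was used to test copy number.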
